A study of Enallax costatus with 10 samples.

How the data were processed

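RNA was measured by sequencing in 10 libraries of the green alga Enallax costatus covering 5 stages of 1 drying and rewetting course with 2 libraries per stage. Per the labels' protocols, cultures were 6 weeks old and were dried as drops of 40 µL on cover glasses. Hydrated drops were taken at 0 h, Early desiccation at 2.5 h (25% of the volume lost), Late desiccation at 7.5 h (60% lost) and Dry at about 24 h, after the drops had been flat for 11 h. Rehydrated drops were taken 1 h after water was added back. Per the labels' protocols, RNA was made into libraries with a kit designed for Arabidopsis that cleaves ribosomal RNA adaptors, and 105 custom oligonucleotides were added for the rRNA of this material.

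Per the submitters' processing notes, the authors used CASAVA 1.4, Trimmomatic 0.35, Bowtie2 2.2, RSEM 1.2.28 and DESeq2, with the version of DESeq2, the role of each tool and the assembly not given in the sources used here. The first deposited table holds expected counts per assembly gene as RSEM estimates them, where a read that matches several sequences is divided among them; 11.4% of its values were not whole numbers. The second deposited table holds a score: the values behave as length-normalised expression that the authors divided by 1 TMM factor per library, judged from the values and the table's name. Its columns summed to between 535618 and 2610432, so these are not plain TPM, and the exact formula is not given in the sources used here. The columns of both tables were matched to samples by replicate number and time code, since their names begin with Scos where the sample titles have Ecos; every stage assignment rests on this match. Both tables list 32478 assembly genes under identifiers in the form that the Trinity assembler writes. The tables do not pair these identifiers with gene names, so the name-based pathway lists drawn up beforehand could not be applied and gave no values. An assembly gene can be a fragment of a gene or 1 of several near-identical copies, and reads shared between copies make single values uncertain.

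Expected counts were rounded to whole numbers and analysed in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 with a minimum count of 10 and a minimum total of 15, which left 16190 genes holding 97% to 99.6% of each library's counts. Library sizes were scaled by TMM, and all 10 libraries entered 1 quasi-likelihood fit with stage as the factor, so that all stages shared an estimate of the spread with 5 residual degrees of freedom. Each of 7 contrasts between stages was tested with glmQLFTest, and a joint test covered any change between stages. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene is called when its adjusted p is under 0.05. CPM values are on TMM-scaled library sizes, and log2 CPM values used a prior count of 2. Log2 fold changes of the contrasts come from each fit and did not use this prior count. Errors are SD over the 2 libraries of a stage unless an SE is named. The SE of an edgeR fold is its absolute value divided by the square root of its F statistic. It therefore follows from the test and is no separate measure of error. Folds against a stage with no counts in either library are lower bounds, taken against 3 counts summed over that stage. Floors cover counting error only, and reads without molecular identifiers are not independent molecules. Intervals are bootstrap intervals over genes, which are not independent replicates, and they do not cover the spread between libraries. The labels do not say that libraries of a stage came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Each pair differed beyond sampling noise, with a chi-square per degree of freedom between 12.1 for Dry and 62.0 for Rehydrated, so no pair was merged.

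Total counts ran from 1974791 to 3867192 per library. In simulated data with the library sizes and spread of these libraries (14577 genes tested, Dry against Hydrated), edgeR recovered 0 of 67 genes changed 2-fold, 1 of 67 changed 4-fold and 15 of 66 changed 8-fold, with 3 false calls among 19. DESeq2 recovered 45 of 66 at 8-fold in the same comparison (16190 genes tested), with 33 false calls among 104. A gene that was not called may therefore still have changed. The simulation changed only these genes in Dry, whereas 2117 genes were called in the real contrast. The adjustment of p-values was then stricter in the simulation, so these rates are not the recovery in the real Dry contrast.

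The rule for named genes, fixed before the data were examined, took the 2 assembly genes with the largest rise and the 2 with the largest fall from Hydrated to Dry among called genes with both Dry libraries on 1 side of both Hydrated libraries and a mean of at least 10 CPM in the higher stage; 1939 genes were eligible. Gene groups fixed beforehand for tables without names were quartiles of mean expression, quartiles of effective length (count divided by score, relative values) and genes of 1 assembly component. Measures of single libraries were compared between stages with an exact permutation test over all 945 ways of pairing 10 libraries, counting pairings at least as tight as the stages. Contrasts that share libraries were set beside 10 simulations of unchanged stages.

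Alternatives fixed before the data were examined were RLE, upper-quartile and total-count scaling, no filter and a filter of 5 CPM in at least 2 libraries, DESeq2 1.42.0, limma 3.58.1 on the log2 of the second table plus 1 or 0.1, the replicate number as a block, fits of the compared stages alone, stricter thresholds, summed components and leaving out each library. Added after seeing the data were a term for a split of the libraries described in the report, fits within each side of that split, and limma voom with estimated library weights. Figures were drawn with matplotlib.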

Results

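The data set follows gene expression in a green alga as drops of culture dried, stayed dry and were rewetted, to show which transcripts change at each of 5 stages. Each stage had 2 libraries. Total expected counts were 3611852 and 2808813 for Hydrated, 3448980 and 3867192 for Early desiccation, 2643958 and 2829841 for Late desiccation, 2497321 and 3713456 for Dry, and 1974791 and 2031426 for Rehydrated (replicates 1 and 2). The assembly genes carry identifiers only, so the results describe numbers, levels and time courses of genes, and name few.

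Libraries differed between stages in how counts were spread over genes. The 100 most abundant genes of each library held 41.5% ± 1.56 of the counts in Hydrated, 46.4% ± 0.0707 in Early desiccation, 60.6% ± 6.01 in Late desiccation and 74.6% ± 15.1 in Rehydrated (SD, n = 2 each), and the Dry libraries were at 54.1% and 55.8%. Libraries of a stage were more alike than chance pairs by the exact permutation test, with 6 of 945 pairings as tight (p = 0.00635, adjusted p = 0.0185 over 5 measures). Counted at a common depth of 1974791, 27322.5 ± 3116 genes were detected in Hydrated, 20622 ± 489 in Early desiccation, 24157.5 ± 1375 in Late desiccation, 17914 ± 165 in Dry and 22578 ± 2514 in Rehydrated (exact permutation p = 0.0138, adjusted p = 0.0230). The library split described below differs in this measure within stages: the set B library had more detected genes than its set A partner in Hydrated (29526 and 25119) and in Late desiccation (25130 and 23185), and both stages with the fewest lie wholly in set A. Genes with at least 100 counts, not adjusted for depth, numbered 4271 ± 656 in Hydrated, 4638.5 ± 109.6 in Early desiccation, 2610 ± 536 in Late desiccation, 2332.5 ± 406.6 in Dry and 832 ± 724 in Rehydrated (exact permutation p = 0.00741, adjusted p = 0.0185). The share of the 10 most abundant genes did not pass the test, with means between 25.3% in Hydrated and 46.2% in Late desiccation (exact permutation p = 0.073, adjusted p = 0.073). A single assembly gene, TRINITY_DN224299_c10_g1, was chosen after its values were seen because it was the most abundant. It held 24.7% ± 4.67 of all counts in Late desiccation, 6.07% ± 3.28 in Hydrated and 1.08% ± 0.226 in Dry. Its share was 7% ± 6.01 in Early desiccation and 9.645% ± 3.288 in Rehydrated (exact permutation p = 0.0317, adjusted p = 0.0396). On TMM-scaled CPM the mean was 226980 ± 191762 in Rehydrated and 211458 ± 65063.5 in Late desiccation, so a peak in Late desiccation holds for shares only. It was not called in any contrast against Hydrated by edgeR.

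**Figure D1:**
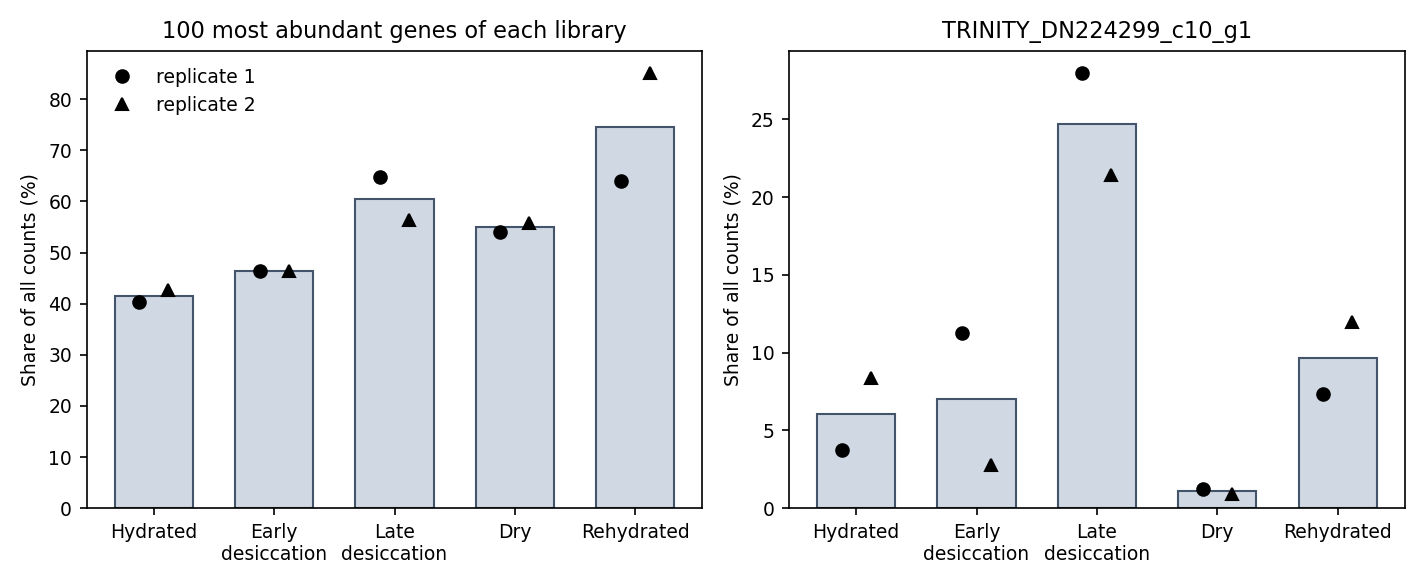
Share of all counts (%) held by the 100 most abundant genes of each library (left) and by TRINITY_DN224299_c10_g1 (right) at each stage; bars are means of 2 libraries, circles replicate 1 and triangles replicate 2. The share of the 100 genes ran from 40.4% in Hydrated replicate 1 to 85.2% in Rehydrated replicate 2, and the single gene held a mean of 24.7% in Late desiccation and 1.08% in Dry.

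Libraries of a stage did not resemble each other equally. Pearson correlations of log2 CPM across genes were 0.57 between the Rehydrated libraries and 0.95 between the Early desiccation libraries, with a median of 0.84 within stages and 0.71 between stages. Early desiccation replicate 1 was closer than the partner to Hydrated replicate 1 (0.89 against 0.84) and Late desiccation replicate 1 (0.88 against 0.81). Late desiccation replicate 2 reached 0.83 with Hydrated replicate 2 and Early desiccation replicate 1, against 0.81 with its partner. Rehydrated replicate 1 was closest to Dry replicate 2 (0.71). The other libraries correlated best with their partner. Rehydrated replicate 2 had 320 genes with at least 100 counts, against 1344 in replicate 1. The libraries also split across the stages. Set B, made of Hydrated replicate 2, Late desiccation replicate 2 and both Rehydrated libraries, held 147 genes with at least 3 counts in each of its libraries and none in the other 6 (set A), whereas the highest count for any other set of 4 libraries was 19. The labels give no batch. Hydrated and Late desiccation have 1 library in each set, Early desiccation and Dry lie in set A, and Rehydrated lies in set B. A fit within set A takes its spread from the Early desiccation and Dry pairs, and a fit within set B from the Rehydrated pair alone.

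While the drops were losing water, the number of genes called varied widely with the fit. Against Hydrated, no gene was called by edgeR in Early desiccation, where 1780 of 16190 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.0587. Likewise no gene was called in Late desiccation, with 1546 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0518. Late and Early desiccation did not differ in any called gene either (1222 genes at an unadjusted p under 0.05, lowest adjusted p 0.658). DESeq2, run on all 32478 genes with its own filtering, called 376, 383 and 56 genes in these contrasts, edgeR without a filter called 67, 49 and 4, and limma voom with library weights called 312, 142 and 0. By edgeR without Rehydrated replicate 1 or 2, 204 or 222 genes were called in Early desiccation, 162 or 233 in Late desiccation, and 2 or 3 between them. Fits of the compared stages alone, which also hold no Rehydrated library, called 579 in Early desiccation, 0 in Late desiccation (2466 at an unadjusted p under 0.05) and 9 between them. Within set A, edgeR called 522 genes in Early desiccation, 878 in Late desiccation and 247 between them, and within set B 0 in Late desiccation (135 at an unadjusted p under 0.05). Each set holds 1 Hydrated and 1 Late desiccation library, so the spread came from the stages held as pairs, and Late desiccation against Hydrated compares single libraries there.

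In drops that had been dry for 11 h, expression differed widely from Hydrated. Dry had 1246 genes higher and 871 lower than Hydrated (13.1% of 16190 tested, edgeR), and the median log2 fold change was 3.05 among the higher and -2.84 among the lower genes. The higher genes took 53% ± 1.05 of all counts in Dry against 19.0% ± 2.76 in Hydrated (SD, n = 2), and the lower genes fell from 6.57% ± 0.63 to 0.36% ± 0.08. Of the 100 most abundant genes of Hydrated, 18 were higher and 9 lower in Dry by edgeR; of the 100 most abundant of Dry, a list that leans to higher genes by its selection, 66 were higher and 0 lower.

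Both named genes that rose were without counts in either Hydrated library. TRINITY_DN216684_c4_g1 reached 509 ± 82.4 CPM in Dry (SD, n = 2; 743 and 1166 counts), at least 1799-fold higher than Hydrated, with a fitted log2 fold change of 13.77 (SE 3.47, edgeR adjusted p = 0.0362). It had 0 and 1157 counts in Early desiccation, 8 and 0 in Late desiccation and 0 in both Rehydrated libraries. TRINITY_DN209631_c7_g3 reached 84.6 ± 23.5 CPM in Dry (112 and 208 counts), at least 299-fold higher (fitted log2 fold change 11.18, SE 1.56, edgeR adjusted p = 0.00421), and had 25 and 0 counts in Rehydrated. Both named genes that fell had no counts in Dry. TRINITY_DN182354_c2_g3 went from 29.2 ± 2.86 CPM in Hydrated (180 and 131 counts) to at least 36.0-fold lower (fitted log2 fold change -9.65, SE 2.02, edgeR adjusted p = 0.0162). Much of this fall was already seen at the earlier stages, although it was not called there. The gene was at 2.13 ± 1.98 CPM in Early desiccation (4 and 20 counts) and 0.695 ± 0.983 CPM in Late desiccation (4 and 0 counts). In Rehydrated it had 5 and 0 counts. TRINITY_DN52758_c0_g2 went from 18.4 ± 7.12 CPM to at least 22.7-fold lower (fitted log2 fold change -8.98, SE 1.59, edgeR adjusted p = 0.0084), after 57.1 ± 5.31 CPM in Early desiccation, and was at 15.9 ± 3.48 CPM in Rehydrated. TRINITY_DN216684_c4_g1 was not called without either Hydrated library (adjusted p 0.109 and 0.115), either Dry library (0.0883 and 0.119), with a term for the library split (0.0607) or by limma voom with library weights (0.29). Its fitted log2 fold change without a library was 13.65, 13.68, 14.00 and 13.63 in that order, 12.88 with the split and 12.40 with the weights. The call of TRINITY_DN182354_c2_g3 was lost without Hydrated replicate 1 (0.0607) and without Dry replicate 1 or 2 (0.0876 and 0.118), and that of TRINITY_DN52758_c0_g2 without Dry replicate 1 or 2 (0.0514 and 0.0741) and by limma on the second table plus 1 (0.0504). Their fitted folds without a library were -9.38, -9.72 and -9.70 for the former, and -9.03 and -9.02 for the latter, which had -2.21 by limma.

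The share of Dry calls that were higher was 58.9% under TMM, 47.4% under upper-quartile scaling and 6.6% under total counts, where the median log2 fold change of all genes moved from -0.50 to -1.96; directions are therefore relative to the scaling. The count of 2117 became 476 or 472 without Hydrated replicate 1 or 2, 1034 or 1041 without Early desiccation replicate 1 or 2, 1233 without Late desiccation replicate 1, 583 or 365 without Dry replicate 1 or 2, and 3994 or 4087 without Rehydrated replicate 1 or 2. It was 1192 with a term for the library split, which remade 53.5% of the calls in the same direction. Within set A, which holds 1 Hydrated library, the median fold of the 2117 genes in the called direction was 2.91 on the log2 scale, against 2.96. These genes were selected as called from the same libraries, so neither value is separate evidence.

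**Figure D2:**
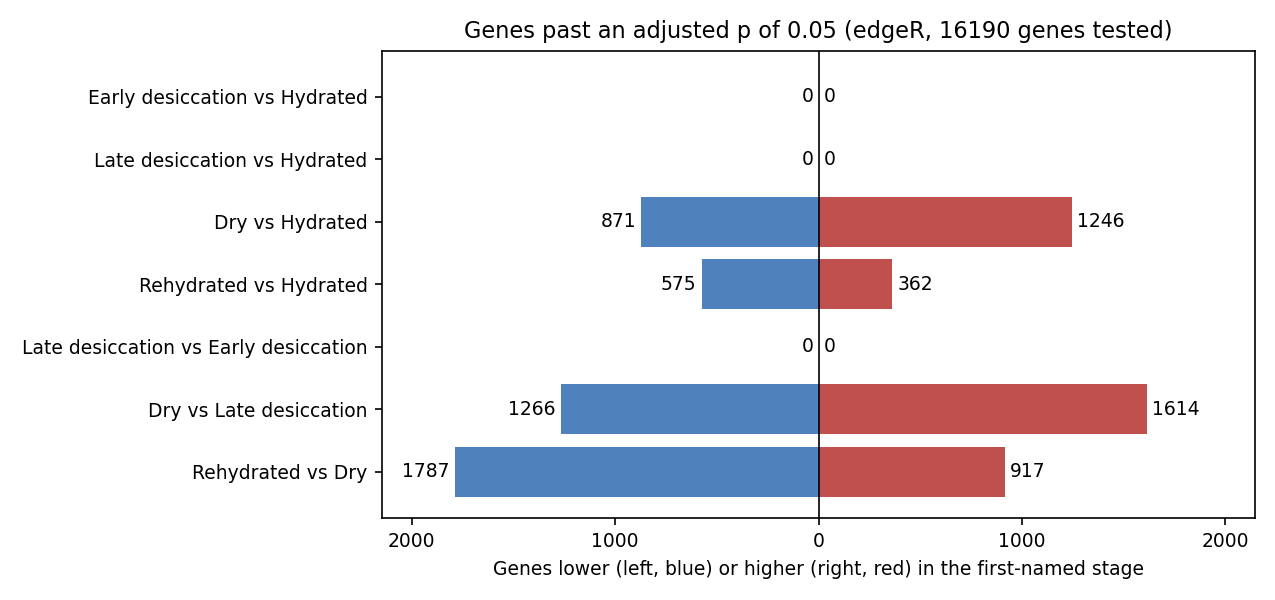
Number of genes called at an adjusted p of 0.05 by edgeR in each of 7 contrasts, with genes lower in the first-named stage to the left in blue and higher genes to the right in red. Counts are 0 in the 3 contrasts among Hydrated, Early desiccation and Late desiccation, and 1246 higher against 871 lower in Dry against Hydrated, relative to TMM scaling (6.6% of these calls are higher under total counts).

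Dry also differed from Late desiccation, the stage before it. Dry had 1614 genes higher and 1266 lower (edgeR; median log2 fold changes 2.83 and -2.87). Of these, 1015 of the higher genes and 543 of the lower genes were called in the same direction against Hydrated. Both contrasts hold the same Dry libraries, so part of this overlap is built in. The share of calls that were higher was 56% under TMM and 12.8% under total counts. The count of 2880 became 1490 or 1494 without Early desiccation replicate 1 or 2, 388 or 367 without Late desiccation replicate 1 or 2, 724 or 336 without Dry replicate 1 or 2, and 4737 or 4847 without Rehydrated replicate 1 or 2; it was 1442 with the split as a term and 4508 within set A.

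An hour after rewetting, expression differed from that of Hydrated drops in the fit of all libraries. Rehydrated had 362 genes higher and 575 lower than Hydrated (edgeR; median log2 fold changes 3.91 and -3.31). The higher genes took 52.0% ± 10.1 of all counts in Rehydrated, against 7.12% ± 1.31 in Hydrated and 17.8% ± 0.75 in Dry (SD, n = 2). Of the 100 most abundant genes of Hydrated, 19 were higher and 17 lower in Rehydrated by edgeR. Of the 100 most abundant of Rehydrated, which lean to higher genes by selection, 75 were higher and 0 lower, and 35 were also among the 100 most abundant of Dry. The share of calls that were higher was 38.6% under TMM and 4% under total counts, but 59.9% at an adjusted p under 0.01 and 83.4% by limma voom with library weights, where the balance of directions turned. Within set B, which holds 1 Hydrated library, edgeR called 0 genes (447 at an unadjusted p under 0.05), a fit of these stages alone called 0 (1880 at an unadjusted p under 0.05), the fit with the split as a term called 500, DESeq2 on all 32478 genes called 1950 and limma voom with library weights 277. Within set B all 937 genes kept their sign, with a median fold in the called direction of 3.37 against 3.53 on the log2 scale. Their median SE was 1.89 there against 0.72. The fit of these stages alone tested 905 of them, and all 905 kept their sign (median 3.45, SE 0.96). With the split as a term, all 937 kept it (median 3.52, SE 0.83). These genes were selected as called from the same libraries, so kept signs were nearly fixed in advance and are no separate evidence. The count of 937 became 38 or 476 without Hydrated replicate 1 or 2, 505 or 506 without Early desiccation replicate 1 or 2, 548 or 517 without Dry replicate 1 or 2, and 2978 or 1633 without Rehydrated replicate 1 or 2.

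Rehydrated also differed from Dry, the stage before it. Rehydrated had 917 genes higher and 1787 lower than Dry (edgeR; median log2 fold changes 3.31 and -2.91). The share of calls that were higher was 33.9% under TMM, 51% under upper-quartile scaling and 29.9% under total counts. Neither set holds libraries of both stages, so no value within a set exists. With the split as a term, 4 genes were called by edgeR (2890 at an unadjusted p under 0.05). Of the 2704 genes, 2701 kept their sign, which their selection from the same libraries nearly fixed in advance. Their median fold in the called direction went from 3.02 to 2.79 on the log2 scale, and their median SE from 0.69 to 0.97. The count of 2704 became 1497 or 1507 without Early desiccation replicate 1 or 2, 682 or 344 without Dry replicate 1 or 2, and 4934 without Rehydrated replicate 1; a fit of these stages alone called 540, of which 368 were higher and 172 lower (68.1% higher, the other way from the joint fit), and limma voom with library weights 1079.

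Across the course, 3561 genes (22% of those tested) were called in the joint test for any stage. This count became 1836 or 1846 without Early desiccation replicate 1 or 2, 1513 or 1108 without Dry replicate 1 or 2, and 6503 or 5524 without Rehydrated replicate 1 or 2. The genes called in Dry lay closer to Hydrated at the stages before. The 1246 genes higher in Dry had median log2 fold changes against Hydrated of 0.37 in Early desiccation, 0.22 in Late desiccation, 3.05 in Dry and 0.97 in Rehydrated, and the 871 lower genes had -0.38, -0.39, -2.84 and -1.16. As shares of counts, the lower genes went from 6.57% ± 0.63 in Hydrated to 3.86% ± 0.63 in Early desiccation, 2.86% ± 0.85 in Late desiccation and 0.36% ± 0.08 in Dry (SD, n = 2), and the higher genes from 19.0% ± 2.76 to 24.7% ± 6.16, 12.6% ± 1.06 and 53% ± 1.05. Of the 1246 higher genes, 723 (58%) fell again in Rehydrated against Dry, 193 were still higher in Rehydrated than in Hydrated, and 5 rose further. Of the 871 lower genes, 292 (33.5%) rose again, 146 were still lower and 11 fell further. Other genes were called after rewetting alone: 125 genes were higher in Rehydrated than in both Hydrated and Dry and not called in Dry against Hydrated, and 304 were lower in the same way. The counts of genes that fell or rose again or were called after rewetting alone rest on the calls of Rehydrated against Dry, which went from 2704 to 4 with the split as a term and to 682 or 344 without Dry replicate 1 or 2. The genes still higher or lower and those called after rewetting alone also need a call of Rehydrated against Hydrated, a count that went from 937 to 38 without Hydrated replicate 1 and, as given above, to no gene within set B or in the fit of those stages alone. These contrasts share libraries, and genes selected in Dry lie far from Hydrated partly by selection.

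**Figure D3:**
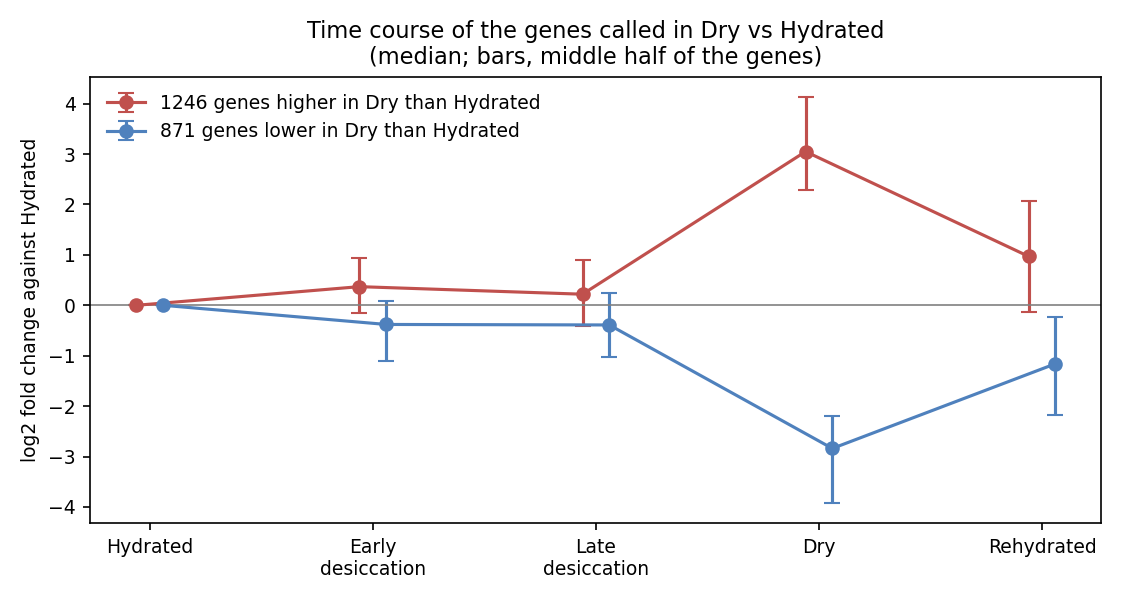
Median log2 fold change against Hydrated at each stage for the 1246 genes higher (red) and the 871 genes lower (blue) in Dry than in Hydrated; bars span the 25th to 75th percentile of the genes. The medians lie at 0.37 and -0.38 in Early desiccation, 3.05 and -2.84 in Dry, and 0.97 and -1.16 in Rehydrated.

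The calls of Dry and Rehydrated against Hydrated overlapped. The 193 genes higher in both compare with 27.9 for independent lists, and the 146 lower in both with 30.9; unchanged stages simulated against the same Hydrated libraries gave an overlap of 0, which is no reference for these counts because unchanged stages yield almost no calls. The values for independent lists take every gene as equally likely to be called. The quartile with the highest mean expression held 781 of the 1246 genes higher in Dry and 241 of the 362 higher in Rehydrated. For lower genes it held 247 of 871 and 300 of 575. Part of the excess may come from this and from the shared Hydrated libraries, which were not divided between the contrasts. The counts of 193 and 146 rest on the calls of Rehydrated against Hydrated limited above. Fold changes in these contrasts correlated across genes at 0.19, against 0.38 in the simulation, and had a covariance of 1.01 against 0.45 simulated. For Early desiccation and Dry, both in set A, the correlation was 0.42 against 0.46 simulated and the covariance 1.79 against 0.46. For Early desiccation and Rehydrated, which lie on opposite sides of the split, the correlation was -0.13 against 0.42 and the covariance -0.49 against 0.46. Genes are not independent replicates.

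Whether drying changes ran back on rewetting was asked with Late desiccation against Hydrated and Rehydrated against Dry, which share no library. Their fold changes had a correlation of -0.04 across genes, and 0 in simulated unchanged stages. The value was 0.311 without Hydrated replicate 2 and -0.255 without Late desiccation replicate 2, both of which lie in set B. For Dry against Hydrated and Rehydrated against Dry, which share the Dry libraries, the correlation was -0.68 against -0.49 simulated, and the covariance -4.82 against -0.62. To avoid sharing a library, 1 Dry library was compared with Hydrated and the other with Rehydrated. With Dry replicate 1 against Hydrated, 323 of 327 higher calls and 78 of 93 lower calls had the opposite sign in Rehydrated against Dry replicate 2; with the Dry libraries exchanged, the counts were 540 of 574 and 131 of 168. Over all genes, between 70.2% and 73.2% had opposite signs in this divided comparison, against 50.6% and 50.7% in unchanged stages simulated with the same division. Each fit had 1 Dry library, which was assumed to vary like the other stages. Dividing the libraries removes shared noise, but both contrasts still contain the true level of Dry. A Rehydrated state unrelated to Hydrated would also give more opposite signs than unchanged stages do, most of all in genes selected in Dry. Opposite signs above the simulated values, here and below, therefore cannot show that changes ran back to Hydrated. The simulation holds no library split, whereas Dry lies in set A, Rehydrated in set B and Hydrated in both. In a test chosen after these values were seen, Dry was compared with 1 Hydrated library. Opposite signs then made up 67.7% and 68.6% with Hydrated replicate 1, which lies in set A as Dry does, and 73.9% and 75.2% with Hydrated replicate 2 from set B, against 50.5% to 50.8% simulated. The correlation was -0.21 and -0.28 with replicate 1, and -0.49 and -0.51 with replicate 2. In these comparisons edgeR called 0 genes in Dry (between 2186 and 2818 at an unadjusted p under 0.05; no other tool was run), and Rehydrated against Dry still crosses the split.

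Calls in Dry were unevenly spread over expression levels. In the quartile of genes with the highest mean expression over all libraries, 781 were higher and 247 lower in Dry than in Hydrated, with a median log2 fold change of 0.51. In the quartile with the lowest expression, 32 were higher and 56 lower, with a median of -1.75. The difference of these medians was 2.27 and ranged from 0.84 to 4.89 over the alternatives, scaling by total counts included. The highest value came without Dry replicate 2. By limma on the second table it was 0.84 with 1 added and 2 with 0.1 added, so it depended on the value added before the log2. The difference also moved with the library split: 0.85 within set A, 0.88 without Hydrated replicate 2 and 1.27 with the split as a term. Without Hydrated replicate 1 it was 2.65. Part of this contrast is built in, because the mean includes the Dry libraries and because abundant genes are easier to call. By effective length, the longest quartile had 461 higher and 405 lower genes, and the shortest 204 and 89. The difference of their median log2 fold changes, longest minus shortest, was 0.37 and ranged from -0.37 to 0.63 over the alternatives. Its sign turned within set A (-0.32), without Hydrated replicate 2 (-0.37) and with the split as a term (-0.17). Without Hydrated replicate 1 it was 0.40. Among 1701 assembly components with several tested genes, 156 pairs of genes from 1 component were both called in Dry against Hydrated, and 97.4% of these pairs changed in 1 direction, against 51.6% of random called pairs.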

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

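Tests chosen after the result was seen were those of depth and stage for the library split, of depth and exchange for Rehydrated replicate 2, and of 1 aberrant library and the split term for the contrast of Rehydrated and Dry; the other tests in this part were written down before their result was seen.

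The response to drying and the state after rewetting differed for 2704 genes, those called in Rehydrated against Dry, which is the test of the difference between the 2 effects against Hydrated. Among them, 18 genes were higher than Hydrated in Dry and lower than Hydrated in Rehydrated, and 1 gene was lower in Dry and higher in Rehydrated. Many more tested genes were called the same way against Hydrated in both stages, 193 higher and 146 lower. The counts of 18 and 1 also need a call of Rehydrated against Hydrated, limited as given above. They were not compared with independent lists. With the library split as a term the difference was called for 4 genes, while 2701 of the 2704 kept their sign. Their median fold went from 3.02 to 2.79 on the log2 scale and their median SE from 0.69 to 0.97. The fold thus became slightly smaller, and the SE, which follows from the fold and the F statistic, grew. Kept signs were nearly fixed in advance, because these genes were selected from the same libraries.

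A set of 4 libraries (Hydrated replicate 2, Late desiccation replicate 2 and both Rehydrated libraries) held genes that the other 6 lacked. Picked from Rehydrated against Early desiccation and Dry alone, 650 genes had 88.6% of their Hydrated counts in replicate 2 (bootstrap interval over genes 86.0 to 90.9), where depth predicts 43.7%, and 86.9% of their Late desiccation counts in replicate 2 (82.5 to 90.9), where depth and stage predict 51.7%; these values argue against depth or stage as the whole cause, although both lie below the bound of 90% set for a plain exclusion. Another organism or strain in those libraries stays open, since the Spearman correlation of the picked genes between Hydrated and Late desiccation replicate 2 was 0.35, between the values set for and against it (0.8 and 0.1). The picked genes held 0.408% of counts or less in any library. A difference of culture or preparation batch stays open and untested, because the labels give none.

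Rehydrated replicate 2 stood apart from its partner, with 85.2% of counts in 100 genes against 63.9%. Depth is argued against, as its total was 1.03 times that of replicate 1. Exchange with a library of another stage is argued against by its correlations, which were higher with replicate 1 than with the next best library by 0.08 (bootstrap interval 0.07 to 0.09), although replicate 1 itself correlated less with replicate 2 (0.57) than with any other library (0.60 to 0.71, highest with Dry replicate 2); a wrong label on replicate 1 was not tested. Loss of long transcripts is argued against, since among abundant genes the log2 ratio to replicate 1 was -0.69 for the shortest minus the longest quartile, opposite to such a loss. A real difference in recovery between the drops stays open and was not tested.

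Rehydrated and Dry differ in many genes, and they lie on opposite sides of the library split. The split measured in Hydrated and Late desiccation alone, signed by the Rehydrated minus Dry direction, had a median of 0.20 on the log2 scale in the called genes (bootstrap interval 0.18 to 0.22), against a median size of 3.02 for the contrast itself, which argues against the split as the whole cause. It had the direction of the contrast in 67.1% of the genes higher and 72.9% of those lower in Rehydrated, so a part may come from it. Without Rehydrated replicate 2, 70.9% of the calls were made again in the same direction. The median fold of the called genes was then 2.66 on the log2 scale, against 3.02. This cannot decide whether that library was the only source, because the genes had been selected with replicate 1 included. Leaving it out also took their median SE, which follows from the fold and the F statistic, from 0.69 to 0.61. That library as a source therefore stays open. The stage itself is a candidate explanation for the rest, as a hypothesis from the same data.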

How the results depend on the processing

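The library split term, the fits within set A or B and limma voom with library weights were chosen after seeing the data. Counts are given in the order Early desiccation, Late desiccation, Dry and Rehydrated against Hydrated, Late against Early desiccation, Dry against Late desiccation, Rehydrated against Dry and any stage, which were 0, 0, 2117, 937, 0, 2880, 2704 and 3561; a contrast left out moved by less than 1.5 times. The causes were not tested unless stated.

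RLE scaling called 3 in Early and 3 in Late desiccation, and upper-quartile scaling 2 and 3. Total counts called 4425 in Dry, 4097 in Rehydrated and 665 between Rehydrated and Dry; the construction leaves composition uncorrected. Without a filter the counts were 67, 49, 1507 in Rehydrated and 4 between Late and Early desiccation, and the stricter filter gave 3 in Early desiccation. DESeq2 called 376, 383, 3177, 1950 and 56, and 6293 for any stage; it was run on all 32478 genes with its own filtering, so tool and filter changed together. In simulation on the filtered genes it made more false calls than edgeR. With limma on the second table plus 1, counts were 10, 18 and 2235 in Rehydrated; plus 0.1, they were 1, 2, 1159, 1575, 1 and 1721. Fits of the compared stages alone, with fewer genes and 2 residual degrees of freedom, gave 579 in Early desiccation, 4607 in Dry, 0 in Rehydrated, 9 between Late and Early desiccation, 5216 between Dry and Late desiccation, and 540 between Rehydrated and Dry. At an adjusted p under 0.01, counts were 595 in Dry, 147 in Rehydrated, 664 between Dry and Late desiccation, 531 between Rehydrated and Dry, and 1189 for any stage, by construction. Summing components gave 2593 in Dry.

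The library split as a term gave 13, 17, 1192, 500, 1442 between Dry and Late desiccation, 4 between Rehydrated and Dry, and 2043 for any stage. Set A alone gave 522, 878, 3646, 247 and 4508, and set B alone 0 in Rehydrated. Library weights gave 312, 142, 3741, 277, 4822, 1079 and 6142 (with 0 between Late and Early desiccation), and 83.4% of the Rehydrated calls were then higher.

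With the replicate block, counts were 13 in Early and 8 in Late desiccation, and the others stayed within 1.5 times. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated over 0.1 in 3 of 10 pairs of stages, those of Hydrated, Late desiccation and Rehydrated with one another (range over all pairs -0.05 to 0.36).

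Leaving out 1 library, the counts ranged from 0 to 222, 0 to 233, 365 to 4087, 38 to 2978, 0 to 3, 336 to 4847, 344 to 4934 and 1108 to 6503. These fits test more genes, because the filter then asks for 1 library, and the lone library is assumed to vary like the other stages. The correlation of Late desiccation and rewetting changes, -0.04, ranged from -0.255 to 0.311 with a library left out, and was 0.124 with limma on the second table plus 1, 0.117 in fits of the compared stages alone and 0.105 with library weights. The call of TRINITY_DN209631_c7_g3 held in all 25 alternatives run for it (adjusted p 1.17e-05 to 0.0486). Over their alternatives the adjusted p ran from 2.59e-06 to 0.29 for TRINITY_DN216684_c4_g1, from 0.000241 to 0.118 for TRINITY_DN182354_c2_g3 and from 8.54e-05 to 0.0741 for TRINITY_DN52758_c0_g2, and no fold changed sign. In simulated Dry against Hydrated data with few changed genes, edgeR recovered 1 of 67 genes changed 4-fold (14577 tested). DESeq2 recovered 26 of 67 (16190 tested), with 33 false calls among 104. Depth was not varied, so its part was not tested.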

Other observations

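The test in this part was written down before its result was seen.

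The stages shared part of their most abundant genes. Of the 100 most abundant genes of a stage, Hydrated shared 64 with Early desiccation, 66 with Late desiccation, 49 with Dry and 43 with Rehydrated, and the fewest, 35, were shared by Dry and Rehydrated. The 100 most abundant genes of Early desiccation held 33 genes that were higher and 3 that were lower in Dry than in Hydrated. Of the 100 most abundant of Late desiccation, 35 were higher and 6 lower in Rehydrated than in Hydrated.

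The genes lower in Rehydrated held 8.86% ± 2.04 of counts in Hydrated, 6.44% ± 0.27 in Early desiccation, 3.47% ± 0.95 in Late desiccation, 3.46% ± 0.29 in Dry and 0.37% ± 0.29 in Rehydrated (SD, n = 2). They were picked for the last of these differences. The most abundant assembly gene had a relative effective length of 0.067, against a median of 1.64 over tested genes.

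Assembly genes of 1 component changed together, with 97.4% of called pairs in Dry moving in 1 direction. Reads shared between parts of a component were predicted beforehand to give opposite changes, which the pairs did not show. That prediction was wrong by design: RSEM divides a shared read in proportion to the parts' levels, so shared reads can also move the parts together. Shared reads and joint regulation therefore cannot be told apart here, and counts of called genes may count a transcript more than a single time; with components summed, Dry against Hydrated had 2593 calls.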
